A study of Mus musculus with 2 samples.

How the data were processed

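The samples were 2 libraries of total RNA from E13.5 mouse limb, forming 1 group with biological replicate numbers 1 and 2 taken from the labels. Per the labels, RNA was extracted with the mirVana method, the fraction longer than 200 nt was kept, ERCC spike-ins were added, and a manual of a low-input cDNA kit is cited among the protocols. The genome build was mm10 per the labels, and the annotation was GENCODE M4 per the text files deposited with the tables. The aligner, the quantifier, their versions and the use of strand are not given in the sources used here.

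For each library the authors deposited a gene table and a transcript table. The expected counts in the deposited tables are model-based estimates that need not be whole, since reads that match several transcripts are divided among them. The deposited TPM values scale these counts by effective length to the same total in each library, and the deposited FPKM values give the same per kilobase and library size, per the file headers. The deposited IsoPct column gives each transcript's percent of its gene's TPM, and further columns hold posterior means and bounds of TPM credibility intervals, per the file headers. Effective length equalled length minus 99 nt for entries long enough to have any, so genes little longer than that have unstable TPM. The gene table held 43346 Ensembl genes, 96 ERCC sequences, 1 phiX row with 0 counts and 26248 rows whose identifiers are bare numbers. The last of these took 0.000187% of the counts in the mean and were left out of library sizes and of every result, as was the phiX row.

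Gene symbols came from a table of Ensembl identifiers and matched 42462 of the 43346 genes (98.0%), which held 99.8% of their counts. Positions, biotypes and transcript names came from GENCODE M21 on the same assembly, which is a later release than that of the tables, and 97.9% of transcript identifiers were found in it. Where 2 identifiers share a symbol, the one with more counts was used. Car9 stood for the listed name Ca9, and Ahsp was matched to no identifier.

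Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM scaling and the common dispersion under a design with an intercept alone, over genes with at least 10 counts in each library and without spike-ins. DESeq2 1.42.0 gave alternative size factors. All other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Log2 ratios between libraries used TMM-scaled counts with 0.5 added. Relative to TMM, size factors from DESeq2 shift all ratios by 0.002 and the spike-in total by 0.023 on the log2 scale. A gene was called detected at 1 TPM or more in both libraries. Ratios of gene pairs used TPM with 0.1 added and were called larger than the spread when both libraries gave the same sign and the mean was above 2 times the pooled replicate SD of 500 genes of like abundance, combined for the pair. Under this rule 32 of the 33 pairs were past the spread, 24 with the first gene higher and 8 with the second. For 38 gene lists (cell types, pathways and other tissues) and 3 RNA classes (ribosomal protein, mitochondrially encoded and histone genes) the members with a mean of at least 10 counts gave a median ratio, which was ranked among 10000 random lists of genes with similar counts.

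The 38 lists, pairs, tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 20 genes with the highest TPM, the 4 highest members and the lowest of each list, all Hox genes, all genes of the pairs, the sex-linked genes, the 12 highest and 12 lowest ratios among genes with a mean of at least 100 counts, and the fixed isoform genes at 10 TPM or more. Members that added nothing are given as counts or ranges, some genes that the rule picks are not named, and further members of the lists are named where they bear on a count. The 3 RNA classes had been fixed for the composition of the libraries alone, and their level counts and ratios were added afterwards. After the data were examined, a correction for length and GC content was added, in which a line through the medians of 50 bins of each was subtracted from the log2 ratio. GC content came from the longest transcript of each gene in GENCODE M21, and 99.5% of genes with a mean of at least 100 counts had a value. A ratio of posterior mean TPM and a condition on the credibility intervals were also added.

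The dispersion, the count of genes over 2-fold apart, the list percentile and the length correction were tested on simulated data, and the other steps were not. The dispersion step returned coefficients of variation of 0.0502, 0.0999 and 0.197 for true values of 0.05, 0.1 and 0.2 over 17193, 17209 and 17121 genes. The count of genes over 2-fold apart recovered 100 of 100 genes changed 4-fold and 100 of 100 changed 8-fold among 13182, with 0 false calls. Those counts were drawn gene by gene with a coefficient of variation of 0.1 and without reads shared between near-identical copies. No change close to 2-fold was drawn, so calls near that limit and calls that rest on shared reads were not tested. The list percentile placed 98 of 100 lists of 15 genes shifted by 0.2 above the central 95% of random lists, and 3 of 100 unshifted ones, over 17979 genes. Here genes varied independently with a coefficient of variation of 0.05 and no length trend, and no shift between 0 and 0.2 was drawn. Those rates therefore need not hold for the lists reported. The length correction brought a simulated correlation of 0.269 to -0.0008 over 13185 genes and kept a shift of 0.5 at 0.505.

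The libraries held 31927117 and 43194518 expected counts, with 23776 and 24159 genes having a count. A count of 0 is compatible with up to 3 counts, or 0.0940 and 0.0695 CPM, and such floors and the counting errors given cover counting error only, because reads are not independent molecules. With 1 group, no test between conditions was made, and with 1 library on each side no p-value is given for differences between replicates.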

Results

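Total RNA longer than 200 nt was sequenced from limbs of mouse embryos of the B6NCrl strain at embryonic day 13.5 (E13.5), when the cartilage models of the digits are forming and the tissue between the digits has not yet regressed. The embryos of both sexes were pooled, each library started from 10 ng of RNA, and synthetic ERCC transcripts were added as spike-ins. The labels give 1 group, E13.5 limb, with 2 libraries numbered as biological replicates, from separate tissue samples that share a donor entry, and they do not say whether forelimbs, hindlimbs or both were taken. Replicate 1 held 31927117 expected counts and replicate 2 held 43194518. With a single group there is no comparison between conditions, so the questions are which genes and cell types the limb expressed, how abundant genes stood to each other, and where the 2 libraries differed. Values written with ± are the mean and SD of the 2 libraries (n = 2), whose independence rests on that numbering.

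The libraries gave nearly the same profile. At least 1 TPM, the deposited length-scaled abundance, was reached in both libraries by 14986 of 43346 genes. These were 13100 of the 21474 protein-coding genes plus non-coding genes and pseudogenes. A further 1058 genes reached that level in a single library. At least 100 TPM was reached by 1703 genes, and at least 1000 TPM by 102 genes. Across all genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho was 0.954. The spread between the libraries beyond counting error, as edgeR's common biological coefficient of variation, was 5.19%. A chi-square of the counts divided by its degrees of freedom was 5.27, where counting noise alone gives about 1, and this excess includes any noise of library preparation. The SD of the log2 ratio between libraries was 0.80 for genes with a mean of 10 to 100 expected counts, 0.35 for 100 to 1000, 0.10 for 1000 to 10000 and 0.08 above 10000, where counting alone gives 0.44, 0.13, 0.04 and 0.02.

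**Figure D1:**
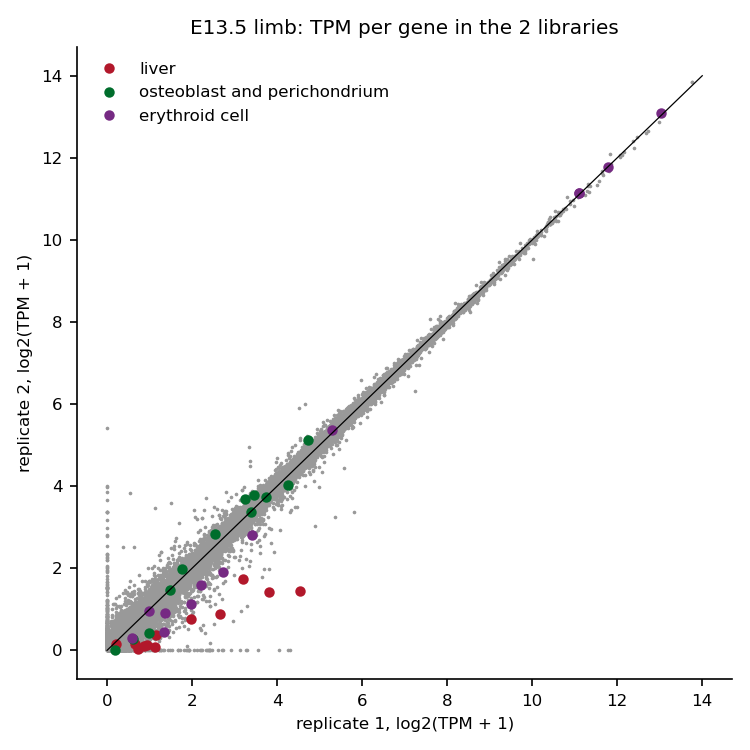
Each point is a gene, with log2(TPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis, and the line marks equal values. Red points are liver genes, purple points erythroid genes and green points osteoblast and perichondrium genes. Most genes lie along the line, while liver genes such as Afp (22.3 TPM in replicate 1 and 1.73 TPM in replicate 2) lie below it.

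Protein-coding genes held 93.0% ± 0.165 of the expected counts, long intergenic non-coding RNAs 1.62% ± 0.0309, mitochondrially encoded genes 1.51% ± 0.107, cytosolic ribosomal protein genes 2.44% ± 0.0632, globins 0.738% ± 0.000559 and replication-dependent histones 0.124% ± 0.00116. These classes overlap, because ribosomal protein genes, histones and part of the globins and mitochondrially encoded genes are also counted as protein-coding. Within the long intergenic class, Gm42418 alone held 158863 expected counts in replicate 1 and 204612 in replicate 2. The spike-ins held 2.09% ± 0.0308 of the counts, and 89 of the 96 spike-in sequences had a read. The 100 most abundant genes made up 24.0% ± 0.103 of total TPM. The highest TPM belonged to Rn7s1 (14219 ± 594) and Rn7s2 (14220 ± 594), near-identical copies of the signal recognition particle RNA gene on chromosome 12. They were followed by the adult alpha-globin Hba-a2 (8591 ± 242), the unprocessed pseudogene Gm28437 on chromosome 1 (7837 ± 436), mt-Atp6 (6598 ± 288), the nuclear RNA Malat1 (6353 ± 217), Actb (5737 ± 77.8), the embryonic beta-like globin Hbb-y (5363 ± 51.2), mt-Atp8 (5111 ± 340) and the ferritin light chain Ftl1 (4541 ± 19.1). The rest of the top 20 were Gm42418, Eef1a1, Ppia, Gm22133, Gm10123, Hba-a1, mt-Rnr2, Hist1h2ap, Ubb and Rpl41, between 3165 and 4336 TPM. The value of Gm22133 rests on an effective length of 10 nt, and the values of Gm28437, Gm10123 and the alpha-globins are uncertain because near-identical copies can share reads.

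Genes 9 to 13 of the HoxA and HoxD clusters, which pattern the limb along its proximal to distal axis, were the most abundant Hox genes, apart from Hoxd9, which was below Hoxa7 and Hoxc10. Hoxa10 reached 165 ± 9.81 TPM, Hoxd12 52.5 ± 4.48, Hoxa9 51.0 ± 2.96, Hoxd13 (chromosome 2, 74668310 to 74671599, mm10) 43.2 ± 3.98, Hoxa11 41.9 ± 6.27, Hoxa13 (chromosome 6, 52257694 to 52260880, mm10) 21.7 ± 1.86 and Hoxd10 21.7 ± 0.191. Hoxd11 followed at 15.9 ± 0.0354, Hoxa7 at 11.4 ± 1.07, Hoxd9 at 8.98 ± 0.134 and Hoxd8 at 6.16 ± 0.113. At least 1 TPM in each library was reached by 8 of 11 HoxA genes, 6 of 9 HoxD genes and 9 of 9 HoxC genes, among which Hoxc10 was highest (9.29 ± 0.127) and Hoxc9 lowest (1.56 ± 0.219). Only 2 of 10 HoxB genes did so, Hoxb2 (3.58 ± 0.523) and Hoxb7 (1.74 ± 0.127). Hoxb13 had 0 counts in both libraries, where 3 counts would correspond to 0.0940 and 0.0695 CPM. Hoxd13 exceeded Hoxd11 by 2.69-fold and Hoxd9 by 4.76-fold, Hoxa11 exceeded Hoxa13 by 1.92-fold, Hoxd13 exceeded Hoxa13 by 1.99-fold and Hoxc10 exceeded Hoxc8 by 3.87-fold, each past the spread of genes of like abundance, although Hoxc10 over Hoxc8 fell within it when 1 TPM was added in place of 0.1. The antisense transcript Hoxa11os (375 ± 26.6 TPM) exceeded Hoxa11 by 8.97-fold, and because the sources used here do not say whether counting used strand, reads of the overlapping pair may have been assigned to either.

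**Figure D2:**
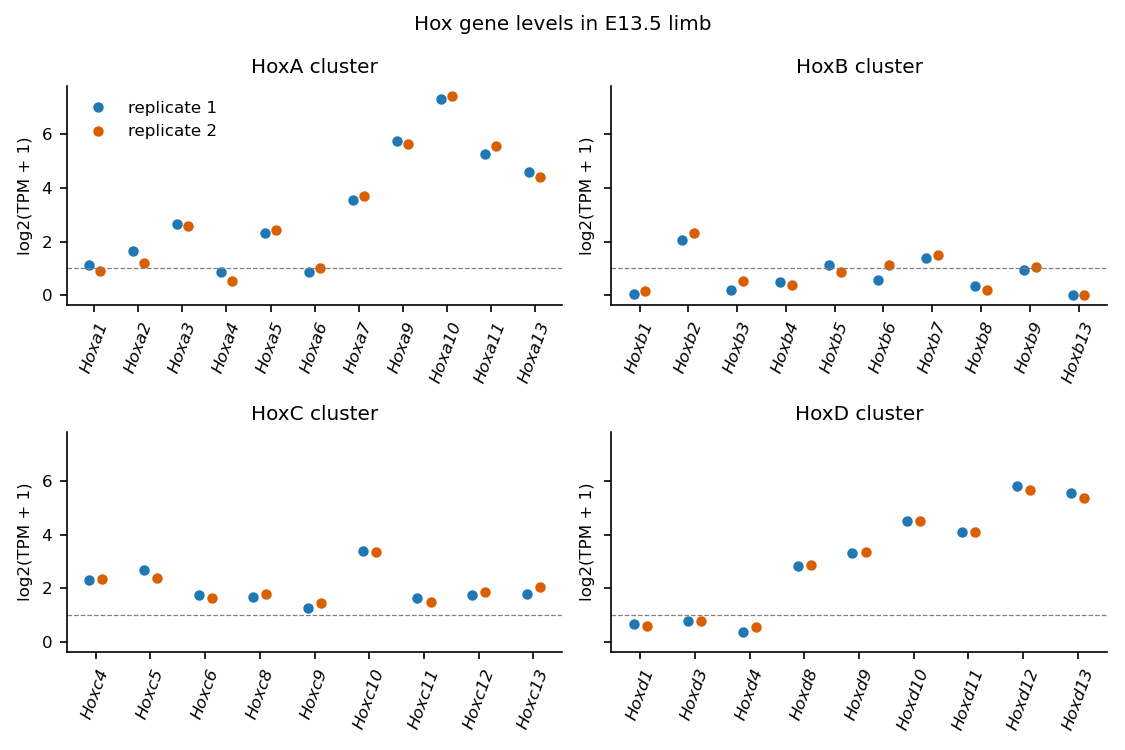
Points show log2(TPM + 1) of each Hox gene in replicate 1 and replicate 2, with genes in cluster order and a dashed line at 1 TPM. The highest level in HoxA is that of Hoxa10 (165 TPM) and in HoxD that of Hoxd12 (52.5 TPM).

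Transcription factors of limb mesenchyme were broadly present, with 24 of 26 at 1 TPM or more. Msx1 reached 253 ± 39.1 TPM, Prrx1 141 ± 11.3, Prrx2 81.7 ± 4.65 and Shox2 52.7 ± 2.23, and Sall3 was lowest at 0.640 ± 0.0141. All 4 genes of limb type identity were detected: the hindlimb factors Pitx1 (chromosome 13, 55825051 to 55836192, mm10; 82.1 ± 11.7) and Tbx4 (22.7 ± 2.44), the forelimb factor Tbx5 (chromosome 5, 119832668 to 119885219, mm10; 25.2 TPM in replicate 1 and 36.5 in replicate 2, mean 30.9) and Isl1 (5.01 ± 1.05). Tbx5 was 1.34-fold above Tbx4 and 2.69-fold below Pitx1. The first of these ratios was past the spread in replicate 2 but not in replicate 1 alone, where its log2 value was 0.05.

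Hedgehog signalling was represented by 9 of 11 genes. Gli3 reached 43.9 ± 1.56 TPM, Smo 43.7 ± 1.97, Hhip 18.4 ± 1.60 and Ptch1 16.4 ± 0.679, and Gli3 exceeded Gli1 by 3.61-fold. The cartilage ligand Ihh stood at 7.06 ± 0.163, while Shh, the ligand of the earlier polarizing region, had 1.00 and 1.72 expected counts in the libraries (0.0200 TPM), so its level lay below what 3 counts would resolve. All 11 genes of retinoic acid and BMP signalling in the interdigit were detected, led by the retinoic acid binding proteins Crabp1 (482 ± 8.56) and Crabp2 (431 ± 0.714), the synthetic enzyme Aldh1a2 (96.4 ± 3.63) and Rdh10 (37.6 ± 0.233), with Nog lowest (7.57 ± 0.651). Aldh1a2 exceeded the degrading enzyme Cyp26b1 by 6.61-fold. Bmp4 was 1.28-fold above Bmp2 in TPM, but this ratio lay within the spread in replicate 1 alone, and Bmp4 was below Bmp2 in expected counts, which are not divided by length. Of the FGF ligands and receptors 9 of 11 were detected, with Fgfr2 at 107 ± 0.141, Fgfr1 at 76.8 ± 2.43, Fgfr3 at 33.1 ± 0.926 and Fgf18 at 14.9 ± 1.01, and Fgf17 lowest at 0.165 ± 0.148. Fgf10 was 2.95-fold above Fgf8, but this ratio lay within the spread with 1 TPM added and in replicate 2 alone.

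Cartilage genes were abundant and complete, while genes of late cartilage and mineralizing bone were low. All 18 chondrocyte genes were detected, with a median of 83.9 TPM. They were led by the cartilage collagens Col2a1 (chromosome 15, 97975602 to 98004695, mm10; 647 ± 73.6), Col9a3 (369 ± 14.7) and Col9a1 (200 ± 4.65) and by their regulator Sox9 (181 ± 9.69), and the lowest was Acan (20.1 ± 3.37). Of the prehypertrophic and hypertrophic genes 7 of 8 were detected, with Pth1r at 76.2 ± 3.37, Mef2c at 42.6 ± 2.91, Ibsp at 16.7 ± 1.83 and Panx3 at 8.83 ± 3.70. The hypertrophic collagen Col10a1 reached 2.48 ± 1.59 TPM, which was 277-fold below Col2a1, and the collagenase Mmp13 0.0700 ± 0.0566. The osteoblast and perichondrium list had 9 of 12 members detected, led by Dlx5 (29.5 ± 6.05), Ibsp, Runx2 (12.4 ± 0.0778) and Alpl (11.3 ± 2.01). Those below 1 TPM were Dmp1 (0.655 ± 0.445), Bglap (0.365 ± 0.219) and Bglap2 (0.0650 ± 0.0919), genes of mature bone. Sox9 exceeded the osteoblast regulator Runx2 by 14.5-fold.

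Joint interzone genes were all detected (11 of 11), with Gdf5 at 86.4 ± 3.39 TPM, Osr2 at 84.3 ± 7.63, Osr1 at 72.6 and Enpp2 at 62.3 ± 8.73. Prg4, the lubricant of the mature joint surface, was lowest at 1.27 ± 0.0990, and Gdf5 exceeded it by 63.2-fold. All 7 tendon genes were detected, with Kera at 75.2 ± 2.13, Tnc at 48.7 ± 8.12, Mkx at 47.3 ± 3.03, the early regulator Scx at 45.3 ± 3.17 and Thbs4 lowest at 23.4 ± 6.24. Scx stood 1.29-fold above the tendon marker Tnmd, a difference that lay within the spread on expected counts. All 20 interstitial matrix genes were detected, led by Col3a1 (1398 ± 88.2), Sparc (1229 ± 39.2), Col1a1 (835 in replicate 1 and 973 in replicate 2) and Col1a2 (709 ± 47.0), with Dpt lowest (5.62 ± 0.509). Col1a1 exceeded Col2a1 by 1.40-fold.

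Genes of differentiated muscle had a median of 58.6 TPM, and those of progenitors and myoblasts 19.8 TPM. Of the myogenic progenitor and myoblast genes 11 of 13 were detected. The differentiation factor Myog (150 ± 11.5 TPM) exceeded the determination factor Myod1 (53.7 ± 6.17) by 2.79-fold, Myod1 exceeded Myf5 by 2.87-fold, and the fusion gene Mymk stood at 38.4 ± 3.46. The progenitor genes Pax3 (0.860 ± 0.0849) and Pax7 (0.755 ± 0.00707) were below 1 TPM and did not differ beyond the spread. Of the differentiated muscle genes 24 of 26 were detected, led by Actc1 (689 ± 4.07), Acta1 (335 ± 8.25), Myl1 (323 ± 5.04) and Tnnc1 (311 ± 1.87), with the adult fast myosin Myh2 lowest (0.115 ± 0.0212). The cardiac-type actin Actc1 was 2.06-fold above the skeletal actin Acta1. Embryonic myosin Myh3 (77.4 ± 9.81) was 3.61-fold above the perinatal Myh8 and 6.62-fold above the slow Myh7.

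In the ectoderm, basal keratinocyte genes dominated. All 20 epidermal genes were detected, with Krt14 at 243 ± 19.2 TPM, Krt5 at 180 ± 21.5, Krt15 at 134 ± 12.6, Perp at 107 ± 6.89 and Grhl2 lowest at 4.43 ± 1.07. Krt5 exceeded the suprabasal Krt1 by 15.1-fold, Krt14 exceeded Krt10 by 23.3-fold and Krt5 exceeded Krt15 by 1.34-fold. Genes of the apical ectodermal ridge, the epithelium that drives limb outgrowth, were low: 6 of 8 reached 1 TPM, with Fgf9 at 11.7 ± 0.0636, Rspo2 at 3.48 ± 0.445, Sp6 at 3.27 ± 0.424 and Fgf8 at 2.62 ± 0.509, and Fgf4 (0.780 ± 0.170) and Fgf17 below.

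Vessels, blood, macrophages and glia were present. All 15 endothelial genes were detected, led by Egfl7 (86.6 ± 1.20 TPM), Ramp2 (61.5 ± 0.877), Plvap (48.4 ± 0.757) and Eng (37.1 ± 1.31), with Sox17 lowest (6.36 ± 1.09). Of 9 pericyte and smooth muscle genes 8 were detected, with Acta2 at 232 ± 0.969, Pdgfrb at 37.8 ± 3.90, Cspg4 at 20.1 ± 1.75, Tagln at 13.6 ± 0.841 and Myh11, a gene of mature smooth muscle, below 1 TPM. Globins mixed embryonic and adult forms: Hba-a1 (3524 ± 35.7) was 6.81-fold above Hba-x (518 ± 27.5), while Hbb-y was 2.42-fold above Hbb-bt (2217 ± 49.2) and 90.9-fold above Hbb-bh1 (59.5 ± 12.4). These folds compare single genes and do not give the balance of embryonic and adult forms. A further adult alpha-globin, Hba-a2, stood at 8591 TPM, and a further adult beta-globin, Hbb-bs, at 2193 TPM in replicate 1 and 2277 in replicate 2. Of 13 measured erythroid genes 9 were detected, and outside the globins the highest was the haem enzyme Alas2 (39.3 ± 1.86). Macrophage and leukocyte genes were detected in 14 of 15 cases (Pf4 37.4 ± 5.61, C1qb 33.5 ± 0.806, Lyz2 26.9 ± 1.22, Tyrobp 25.9 ± 1.86, Cd163 0.0100 ± 0.0141). Schwann cell precursor genes were detected in 7 of 9 cases (Ngfr 26.6 ± 3.03, Erbb3 13.3 ± 1.83, Gfra3 10.6 ± 0.594, Fabp7 8.32 ± 0.849, Foxd3 0.645 ± 0.0354). Melanoblast genes were near the limit, with 3 of 6 detected and Kit highest at 8.11 ± 0.636.

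Neuronal genes were detected in part. Of 15 genes 7 were detected, among them Stmn2 (11.6 ± 0.778 TPM), Nefm (10.5 ± 0.106), Nefl (9.00 ± 0.339) and Tubb3 (6.78 ± 1.46), which encode axonal cytoskeleton proteins, while Chat was at 0.0150 ± 0.0212. No member of the lists for heart (8 genes, highest Myl2 at 0.790 ± 0.184), lung, gut and kidney (9 genes, highest Cdx1 at 0.165 ± 0.0495) or pluripotency and germ cells (7 genes, highest Ddx4 at 0.695 ± 0.0919) reached 1 TPM in both libraries. Of the 12 liver genes 3 did, and these differed between libraries as given further on.

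**Figure D3:**
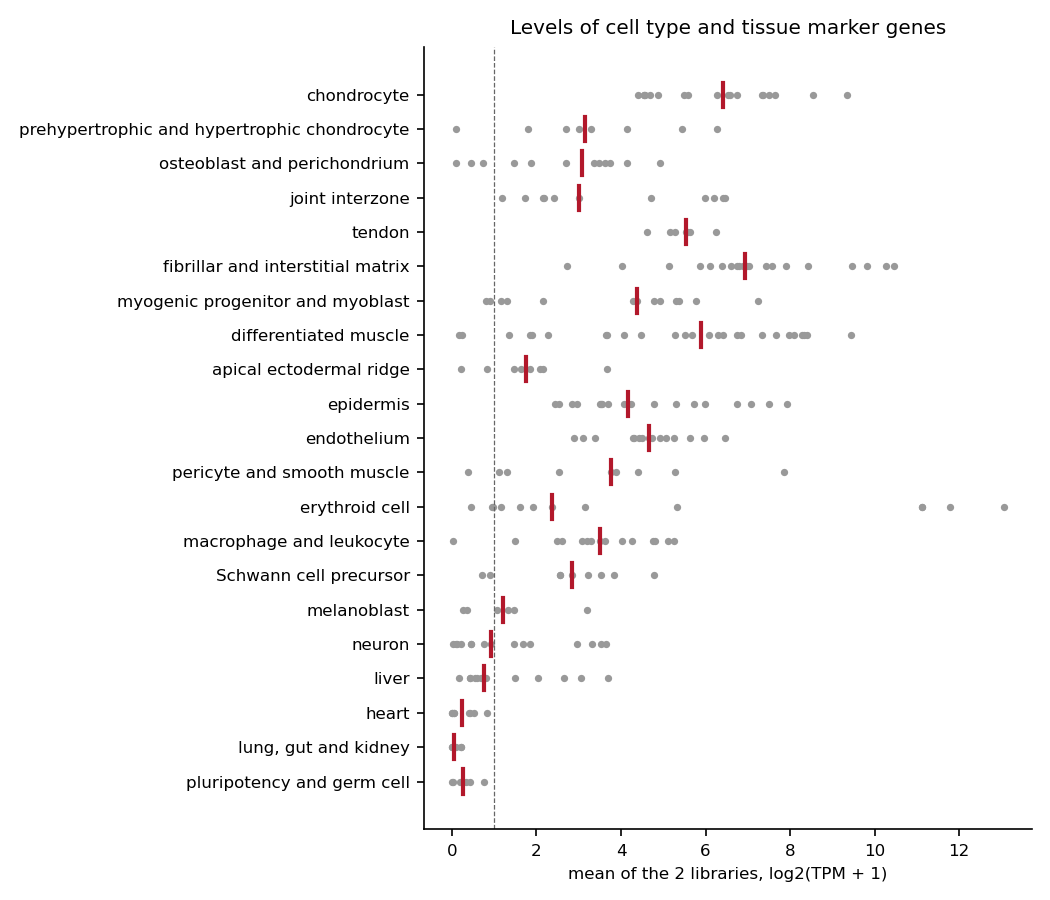
Each grey point is a marker gene of the named cell type or tissue, at log2(TPM + 1) of the mean of the 2 libraries, the red bar is the list median and the dashed line is 1 TPM. The medians of chondrocyte genes (83.9 TPM) and interstitial matrix genes (121 TPM) lie above the line, and that of the heart list (0.185 TPM) lies below it.

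All 21 cell cycle genes were detected with a median of 128 TPM (Cdk1 346 ± 27.3, Birc5 261 ± 8.53, Top2a 225 ± 3.30, Tyms 214 ± 5.71, Mki67 lowest at 31.7 ± 0.0354). All 18 imprinted genes were detected, many of them fetal growth genes at high levels: Gnas 1609 ± 5.13, Mest 1574 ± 116, Igf2 1040 ± 3.15 and Meg3 994 ± 28.3, with Kcnq1ot1 lowest at 5.12 ± 0.396. Igf2 exceeded H19 by 1.40-fold and Igf1 by 22.2-fold, and the methyltransferase Dnmt3a exceeded Dnmt3b by 17.8-fold. As the pooled sexes imply, Xist (23.3 TPM in replicate 1 and 26.7 in replicate 2) and the Y-linked Eif2s3y (37.9 ± 7.31), Ddx3y (28.0 ± 1.94), Uty (13.4 ± 1.25) and Kdm5d (9.46 ± 0.240) were all present in both libraries.

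Among metabolic and stress genes, all 12 hypoxia and glycolysis genes were detected (Eno1 1466 ± 18.2 TPM, Ldha 1370 ± 6.53, Aldoa 525 ± 2.11, Bnip3 111 ± 0.325, Car9 2.35 ± 0.608). Of the immediate early and heat shock genes 12 of 14 were detected, led by Jun (84.2 ± 0.438), Ier2 (60.2 ± 0.530), Btg2 (23.0 ± 0.651) and Dusp1 (15.1 ± 0.785), with Fosb lowest (0.180 ± 0). All 12 housekeeping genes were detected, from Actb down to Tbp (41.9 ± 1.20). Ribosomal protein genes were detected in 81 of 83 cases, led by Rpl41 (3165 ± 144) and Rps19 (2138 ± 17.7). Mitochondrially encoded genes were detected in 15 of 37 cases, and the other 22 are transfer RNAs shorter than the 99 nt subtracted for effective length, so that the tables give them no value other than 0. Replication-dependent histones were detected in 52 of 64 cases, led by Hist1h2ap (3228 ± 46.8) and Hist1h4d (373 ± 8.45), and members of this family share near-identical sequence. Nuclear and non-coding RNAs were detected in 5 of 6 cases, with Malat1, Rn7sk (340 ± 6.63), Rpph1 (108 ± 1.03) and Neat1 (6.11 ± 0.601) highest and Terc (0.385 ± 0.0778) lowest.

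Ratios of gene pairs depended on division by length and, for a gene at very low TPM, on the amount added before the ratio was taken. On expected counts 10 of the 33 pairs moved by more than 1.5-fold: the log2 ratio of Igf2 over Igf1 went from 4.47 to 2.60, of Hoxa11 over Hoxa11os from -3.16 to -1.95, of Aldh1a2 over Cyp26b1 from 2.73 to 1.65, of Tbx5 over Pitx1 from -1.42 to -0.62, of Fgf10 over Fgf8 from 1.56 to 3.71, of Gli3 over Gli1 from 1.85 to 2.61, of Col2a1 over Col10a1 from 8.12 to 8.80, of Ihh over Shh from 5.90 to 7.74, of Bmp4 over Bmp2 from 0.35 to -0.68 and of Pax3 over Pax7 from 0.16 to -0.46. With 1 TPM added, Ihh over Shh was 2.98 and Gdf5 over Prg4 5.27. Shh (0.0200 TPM) lay below even the 0.1 TPM added, so the amount added largely sets Ihh over Shh, and its move on expected counts cannot be put down to length.

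Transcript usage was close between the libraries. Among 6782 genes with more than 1 annotated transcript and at least 10 TPM, the most abundant transcript held a median of 67.9% of the gene's TPM, and it was the same transcript in both libraries for 6406 genes (94.5%). For those genes its share moved by a median of 2.19 percentage points. Pyruvate kinase Pkm (1080 TPM in the mean) was almost entirely Pkm-201 (95.1% ± 0.368), which carries the downstream alternative exon at chromosome 9, 59675568 to 59675734 (mm10), known as the exon of the M2 form. Pkm-202, with the upstream exon of the M1 form at 59675029 to 59675195, held 4.87% ± 0.368. For Col2a1 the 2 leading transcripts were Col2a1-201 (54.6% ± 4.96) and Col2a1-202 (40.2% ± 4.99). They differ by exon 2 at chromosome 15, 98000403 to 98000606 (mm10), 204 nt long, which only Col2a1-201 contains and which chondroprogenitors are known to include. Mef2c was divided between Mef2c-202 (49.0% ± 0.495) and Mef2c-203 (46.0% ± 0.948), Tpm2 between Tpm2-202 (47.3% ± 0.106) and Tpm2-203 (45.0% ± 1.68), and Cd44 between Cd44-207 (52.6% ± 2.83) and Cd44-203 (39.8% ± 2.94).

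For the other fixed genes at 10 TPM or more, the leading transcript of Mef2a held 53.6% ± 0.969, of Tbx3 51.3% ± 3.90, of Sox6 50.4% ± 0.771, of Enah 46.4% ± 2.91, of Fn1 41.2% ± 5.61, of Meis1 39.3% ± 0.368, of Fgfr1 36.9% ± 0.714, of Tpm1 35.2% ± 0.651, of Ctnnd1 35.1% ± 0.0636, of Fgfr3 33.0% ± 3.29, of Sox5 29.1% ± 2.47, of Meis2 27.8% ± 7.05, of Fgfr2 27.8% ± 0.0636, of Runx2 25.6% ± 1.48 and of Tnnt3 24.2% ± 0.148. By posterior mean TPM the leading transcript of Meis2 held 18.2%, near the 17.2% of its second transcript, and that of Ctnnd1 held 27.5%. The leading transcripts of Sox5 (351 nt) and Meis1 are annotated as non-coding processed transcripts, and the second transcript of Fn1 (33.6% ± 3.30) is annotated as a retained intron. Vegfa was left out because its gene TPM (3.69 in the mean) was below 10.

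Between the 2 libraries most gene groups kept their level, and some stood apart. Each list's median log2 ratio of replicate 2 over replicate 1 was set against 10000 random lists matched on mean expression. As 1 library stands against 1 library, the percentile describes these libraries and no p-value applies. Of 38 lists with a percentile, 16 fell outside the central 95%, with 8 higher and 8 lower in replicate 2. About 1.90 would fall outside by chance if genes within a list varied independently, as they do in the random lists. Members of a list that vary together can raise that number. Without the ribosomal protein, mitochondrially encoded and histone genes, which were added to the lists later, 14 of 35 fell outside. The lists for heart, for lung, gut and kidney, and for pluripotency and germ cells had no percentile, as only 2, 1 and 2 members had enough counts. The ratio also followed gene length: across 7601 genes with a mean of at least 1000 counts, which are not independent, Spearman's rho between ratio and length was 0.464. The fifth of these genes with the shortest transcripts (median 1075 nt) had a median log2 ratio of -0.05, and the fifth with the longest (median 5197 nt) had 0.08. With the trend of length and GC content taken out, 12 lists stood outside, 11 of them among the 16. The list that came in anew was Hedgehog signalling, with a median of -0.08 and 7 of 10 genes lower, against -0.05 and inside the random range before.

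The lists lowest in replicate 2 were liver and erythroid genes. All 10 liver genes with enough counts were lower, with a median log2 ratio of -3.04. Afp (chromosome 5, 90490737 to 90508907, mm10), the main serum protein of the fetus, had 925 expected counts in replicate 1 and 95 in replicate 2, a log2 ratio of -3.71, and the log2 ratios of Apoa2, Alb and Apoa1 were -2.85, -2.63 and -1.79. For 9 of 13 erythroid genes the ratio was below 0 and the list median was -0.70. Of these 9, Hba-a1 (-0.06) was close to 0 and the other 8 were not globins, among them Rhag (-2.03), Gata1 (-1.02) and Klf1 (-0.86), while Hba-a2 (0.04), Hbb-bs (0.02), Hbb-bt (0.03) and Alas2 (0.09) were near 0. With genes of at least 100 counts alone the erythroid median was -0.02 and inside the random range, where 5 of the 9 non-globin genes are left out. Mitochondrially encoded genes were lower in 15 of 15 cases (median -0.16), and in 13 of 15 cases with a median of -0.10 once the length and GC trend was taken out. Joint interzone genes were lower in 7 of 11 cases (median -0.11). The sex-linked list (median -0.11) joined genes that moved apart, since its 4 Y-linked genes were lower and Xist was higher. Ribosomal protein genes (median -0.05), housekeeping genes (-0.04) and embryonic globins (-0.11) also lay below the random range, but not once the length and GC trend was taken out (-0.01, -0.01 and -0.06), and the housekeeping list was also inside by the ratio of TPM.

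Cartilage, bone, tendon and surface ectoderm lists were higher in replicate 2, while the joint interzone list was lower, as given above. The osteoblast and perichondrium median log2 ratio was 0.28, with 7 of 10 genes higher, but 0.15 and at the edge of the random range by the ratio of TPM. The higher genes included Dlx3 (0.47), Dlx5 (0.39), Alpl (0.35) and Sp7 (0.32), and Dmp1 (-1.52) and Ibsp (-0.24) were lower. The apical ridge median was 0.30, with 7 of 7 genes higher, although most were under 5 TPM. Chondrocyte (0.11, 12 of 18 higher), tendon (0.12, 6 of 7), epidermis (0.12, 14 of 20) and matrix genes (0.05, 16 of 20) were outside the random range with and without the length trend, although with the trend taken out 12 of 20 genes were higher in the epidermis and in the matrix list. Hypertrophic (0.13) and pericyte genes (0.17) were outside it as deposited but inside after the trend was taken out, at 0.07 and 0.09, and the hypertrophic list was also inside by the ratio of TPM and at the edge of the range with at least 100 counts or the spike-in total. Within the chondrocyte list, Comp (0.62), Snorc (0.53) and Acan (0.32) were higher in replicate 2, and Sox5 (-0.21), Col9a2 (-0.16) and Sox9 (-0.13) were lower. Of the limb type genes, Tbx5 was higher in replicate 2 (36.5 against 25.2 TPM, log2 ratio 0.52), as was Isl1 (0.69), and Pitx1 (-0.33) and Tbx4 (-0.25) were lower, so that the list as a whole (median 0.13) stayed inside the random range.

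**Figure D4:**
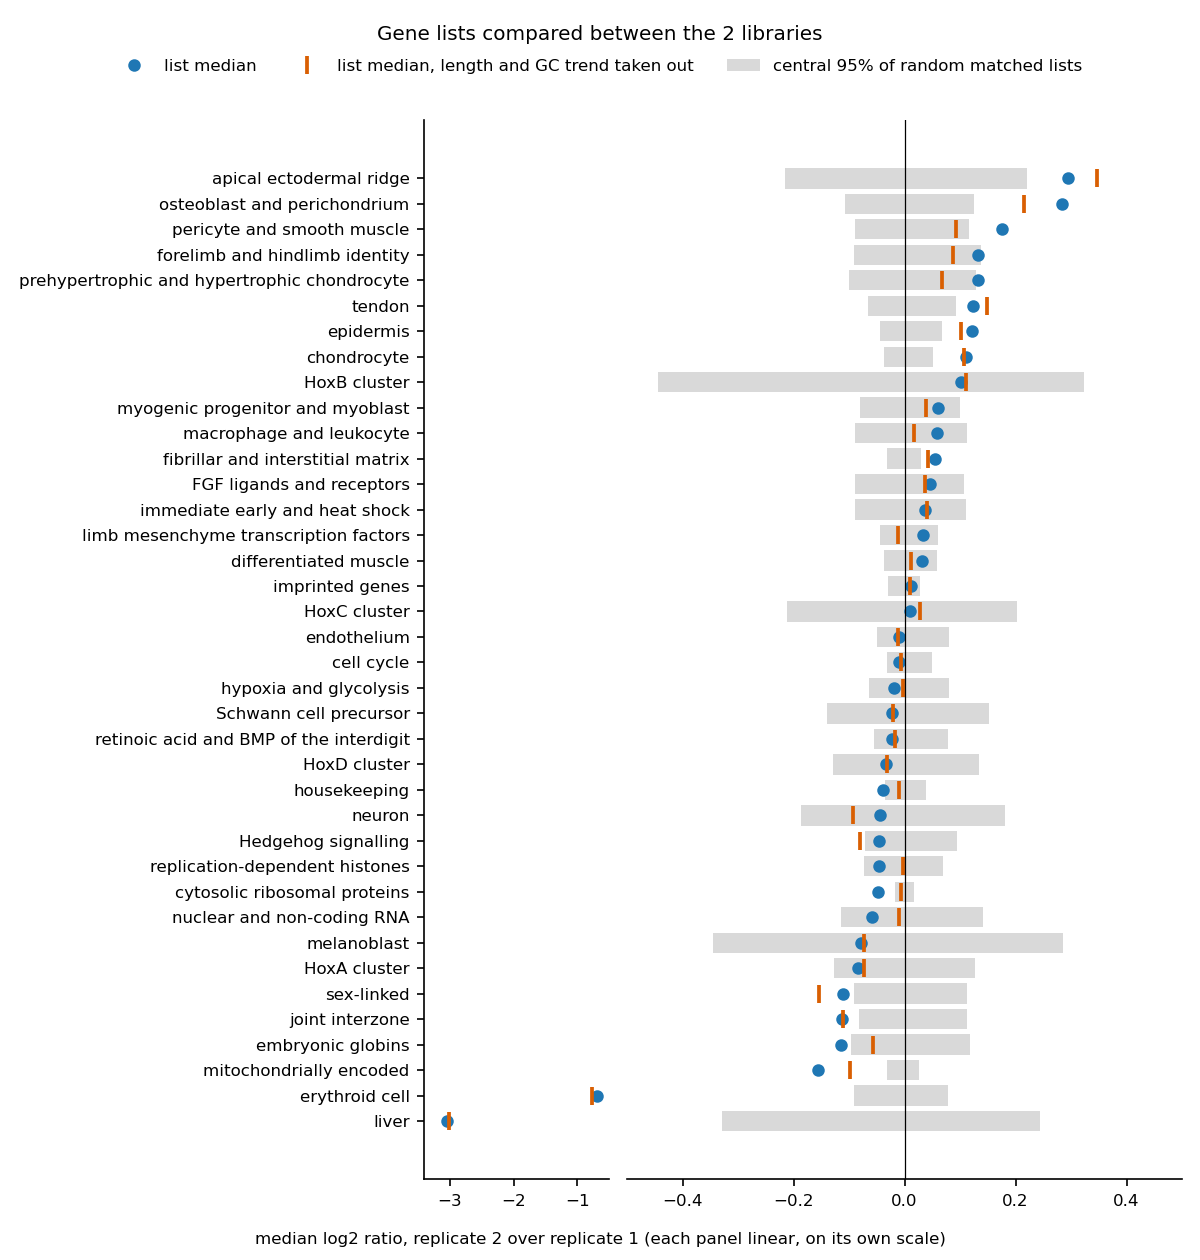
Blue points give each list's median log2 ratio of replicate 2 over replicate 1, orange marks the same with the length and GC trend taken out, and grey bars the central 95% of 10000 random matched lists, in 2 panels with linear scales of their own. Liver (-3.04) and erythroid genes (-0.70) lie far to the left, and apical ridge (0.30) and osteoblast genes (0.28) lie farthest to the right.

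Of 13185 genes with a mean of at least 100 expected counts, 19 were more than 2-fold apart, 7 higher in replicate 2 and 12 higher in replicate 1, and 87 were more than 1.5-fold apart. None of the genes with a mean of 1000 counts or more was over 2-fold apart. For 10 of the 19 the authors' credibility intervals of TPM did not overlap between libraries. Among these were Smpd3 (2.65-fold), Col10a1 (2.61-fold) and the long non-coding RNA Gm28592 (2.27-fold) higher in replicate 2, and Afp (13.0-fold), Alb (6.21-fold), Apoa1 (3.47-fold), the pseudogene Gm6158 (2.11-fold), the blood group gene Rhd (2.06-fold) and the iron carrier Trf (2.05-fold) higher in replicate 1. By the ratio of TPM, Rhd (log2 ratio -0.92) and Trf (-0.66) were not over 2-fold apart. The other 9 had overlapping intervals. Among them Gm4294, Rpl7a-ps11, Gm14440 and ENSMUSG00000103508.1 had 0 expected counts in replicate 1, and Gm14288 had 0 in replicate 2. No fold is given for these 5, whose credibility intervals overlap although the estimate in 1 library is 0. By the log2 ratio of posterior mean TPM, Gm14440 was level (0.03) and Rpl7a-ps11 turned around (-0.73), while Gm4294 (2.17), ENSMUSG00000103508.1 (2.64) and Gm14288 (-0.77) kept their direction. Pseudogenes made up 6 of the 19 against 236 of the 13185. The 12 highest ratios also took in Gm4737, Slc15a2, Gm9755, Sp9 and Panx3, and the 12 lowest Rpl35a-ps3, Gm8226, Gm21541 and Gm10359, several of them members of families with near-identical copies.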

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

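The count on these rows was made after the files were seen. The tables carry 26248 rows whose identifiers are bare numbers, with a median length of 73 nt. They are outside the gene annotation and were used in no comparison, yet reads were assigned to them: 72.0 expected counts in replicate 1 and 64.0 in replicate 2, above the 3 counts that a count of 0 allows. The counts fell on 6 rows in replicate 1 and 8 rows in replicate 2, of which 5 were shared, and a single row held 62.0 and 49.0 of them. Only 63 of these rows are long enough to have an effective length above 0. What the rows represent is not given in the sources used here, and no biological explanation was tested. With 2 samples in 1 group, neither an outlying sample nor a difference between groups was examined.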

How the results depend on the processing

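The alternatives with the length and GC trend, posterior mean TPM and credibility intervals were chosen after seeing the data. Counts of detected genes stayed within 1.5 times of 14986 under the other thresholds and in each library alone, as did the number of list genes detected. The number of lists outside the random range was 14 or 15 with TPM ratios, at least 100 counts or the spike-in total, and 12 with the length and GC trend taken out. The number of genes over 2-fold apart was 19 with DESeq2 size factors and 22 by TPM ratio, but 443 at a mean of at least 10 counts and 0 at 1000. Of the 443, 424 had a mean of 10 to 100 counts, where the spread between the libraries was widest. The cause of the spread beyond counting error was not tested. The number over 2-fold apart was 12 by posterior mean TPM and 10 where credibility intervals did not overlap. The second condition removes genes by construction, and for the first the cause was not tested. Pearson's r was 0.987 with 0.1 TPM added, 0.996 over genes at 1 TPM or more and 0.996 on FPKM, and the biological coefficient of variation was 5.19% with DESeq2 size factors, 5.38% with hardly any filter and 4.81% at 100 counts or more. The median share of the leading transcript was 65.7% by posterior mean TPM, 71.6% for genes at 50 TPM or more and 67.9% in each library alone. The top 100 genes held 24.2% of TPM without spike-ins and mitochondrial genes. The log2 ratio of Bmp4 over Bmp2 turned to -0.68 on expected counts, which follows from leaving out division by length. Expected counts moved 10 of the 33 pairs by more than 1.5-fold. They also do without the 0.1 TPM added, and Shh stood at 0.0200 TPM, so the move of Ihh over Shh cannot be put down to length. Of the 33 pairs, 30 to 31 were past the spread under each alternative. Genes with 10 to 100 counts differed between the libraries by an SD of 0.80 on the log2 scale, where counting alone gives 0.44. Leaving out a replicate gives no value for the results that compare the libraries. No paired analysis was possible because there is a single group.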

Other observations

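The tests in this part were chosen after the results they bear on were seen. The ratios of the fixed lists and the length trend were known when the tests on paralogs, blood, HoxC genes, chondrocyte genes and the length and GC trend were written. The second liver list was written before its own values were seen, but for a pattern already seen in the fixed liver list. The design holds a single group, so no biological explanation that the labels name was tested, and each reading here is a hypothesis about 2 libraries.

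Liver genes and genes of red cell precursors were higher in replicate 1. Sharing of reads between paralogs is argued against by the 9 liver genes with whole counts in both libraries, whose median log2 ratio was -3.24, and the trend of length and GC content by the liver median of -3.01 after it was taken out. More circulating blood in replicate 1 is argued against by the adult globins. Their median log2 ratio was 0.0252, while that of 9 non-globin erythroid genes was -0.86. The 3 embryonic globins were not part of that test. Their median was -0.11 with 2 of 3 lower, and -0.06 and inside the random range with the length and GC trend taken out. A candidate explanation is RNA of liver cells in the replicate 1 library. A second list of 24 liver genes, written before its values were seen, had a median of -2.14 over the 16 with enough counts. Of these, 15 were lower in replicate 2. As it holds further genes of a kind already seen lower, the list cannot separate liver cells from another source of the same transcripts. The fetal liver is the site where red cells form at this stage, but Serpinc1 (-0.12) and Cps1 (0.15) did not follow, Afp reached only 22.3 TPM in replicate 1, and whether the precursor genes came from the same source was not tested.

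Tbx5 was higher, and Pitx1 and Tbx4 were lower, in replicate 2. The difference between the log2 ratio of Tbx5 and the mean of the other 2 was 0.81, and 0.76 with the length and GC trend taken out, which argues against that trend as its cause. A different share of forelimb and hindlimb tissue in the 2 samples may underlie it, and the labels do not give the limb type. Isl1 (0.69), known from early hindlimb, was higher together with Tbx5. Whether Isl1 marks hindlimb tissue at this stage was not tested, so its ratio does not decide for or against different shares. The question of shares was put to Hoxc4 and Hoxc5, known from forelimb, and Hoxc10 and Hoxc11, known from hindlimb. Their mean ratios differed by 0.0831 with a standard error of 0.19. These 4 genes thus did not show a shift as large as 0.81. The log2 ratios were 0.01 for Hoxc4, -0.16 for Hoxc5, -0.05 for Hoxc10 and -0.27 for Hoxc11. The result set to count against different shares was a difference in the opposite direction, which equal shares would not give. How far these genes would move with a change of share was not tested, so the question stays undecided.

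Osteoblast genes, and with less certainty hypertrophic cartilage genes, were higher in replicate 2. With the length and GC trend taken out, tendon (0.15), epidermis (0.10) and apical ridge genes (0.35) were also higher. The shift was thus not confined to the skeleton. Joint interzone genes went the other way, with a median of -0.11 and 8 of 11 genes lower after the same correction. The osteoblast and hypertrophic lists, joined after their ratios were seen, had a median log2 ratio of 0.26, and 0.19 with the length and GC trend taken out, above the upper random limit of 0.08 and with 12 of 15 genes higher, which argues against that trend as the whole cause. This rests on the osteoblast list (0.22 after the correction, but 0.15 and at the edge of its random range by the ratio of TPM), as the hypertrophic list alone was 0.07 and inside its random range. A larger share of cartilage of every stage could also raise these genes, and the chondrocyte list, at 0.11 after the correction with 12 of 18 genes higher, lay between the bounds set for it, so that this cannot be told apart from a change confined to the later genes. Sox9 (-0.13), Sox5 (-0.21), Sox6 (-0.11) and, at few counts, the still later genes Dmp1 (-1.52) and Mmp13 (-1.81) were lower in replicate 2, and a small difference in the age of the embryos stays open and was not tested.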
